A study of Mus musculus with 4 samples.

How the data were processed

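RNA was measured in whole right adrenal glands of adult male C57BL/6 mice 1 h after injection of dexamethasone or PBS, with 5 mice per group. Per the labels, surrounding fat was trimmed, each gland was snap-frozen, and the glands of each group were pooled into 2 replicates, of 2 and 3 mice. Total RNA was extracted with a column kit and libraries were made with a NEBNext Ultra RNA kit for paired-end Illumina sequencing. The replicates are pools of different animals, so the spread between them holds both animal and handling differences, averaged over 2 or 3 mice.

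The deposited table gives whole-number read counts per gene, not normalized, for 54532 mouse gene identifiers with symbols, coordinates, biotypes and a gene length. Per the submitters' processing notes, CASAVA 1.8, STAR 2.5 and HTSeq 0.6.1 were used with the mm10 (GRCm38) genome; the notes give no role or order for the tools. The settings of counting, including whether strand was used, are not given in the sources used here, so genes that overlap another gene and antisense genes cannot be told from their partners, and reads shared by near-identical copies may be lost or divided. The table's columns carry initials and a number; D was read as dexamethasone, S as saline, the vehicle, and the number as the replicate, while other letters in the column names are not explained in the labels. Of the identifiers, 54495 were in GENCODE release M21 of GRCm38, and 98.3% of these had the same chromosome, start and end there. How the authors computed the deposited gene length is not stated. It is not the span between the coordinates: Itgb3, at 104608000 to 104670476 of chromosome 11, has a listed length of 5901 bases.

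Genes were kept with filterByExpr by group, which left 16027 of 27040 genes with at least 1 count. Counts were scaled with TMM factors (1.04, 1.03, 0.986 and 0.951 for dexamethasone replicates 1 and 2 and PBS replicates 1 and 2) and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with the group as the sole term, which left 2 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05 and no fold limit. Fold changes are dexamethasone over PBS on the log2 scale, no library was left out, and standard errors are the size of the log2 fold change divided by the square root of its F statistic. CPM values use the TMM-scaled library sizes, with a prior count of 2 where logs were taken. Standard errors and p-values rest on the spread between pools, not between mice. The fit draws each gene's spread toward that of other genes, so a standard error is not that gene's own spread alone. The biological coefficient of variation was 0.149. Replicates were compared before averaging: counts of the 2 dexamethasone libraries differed by a chi-square of 26.3 per degree of freedom and those of the 2 PBS libraries by 33.8, far above sampling noise, so none was counted as a repeat of another.

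Gene lists were written before the data were examined, 29 in all: pathways, cells of the adrenal, other cells the gland could hold, and signs of RNA quality. They are named in the results, with some genes in several lists. Lists with at least 3 measured members, 27 in all, were tested with camera (limma 3.58.1) on log2 CPM, two-sided, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. With an estimated correlation camera has 2 residual degrees of freedom, and no list passed (1 at an unadjusted p under 0.05). Named genes followed a rule set before the data were examined. It took the 12 higher and 12 lower genes with the smallest p among those that passed and whose libraries did not overlap, leaving out predicted genes, pseudogenes and genes without a symbol. It added up to 4 members of each list by p and all members that passed, and Fkbp5, Tsc22d3, Per1, Star, Mc2r, Nr4a1, Fos, Cyp11a1, Cyp11b1, Cyp11b2, Th, Pnmt and Nr3c1. In all it gave 145 genes, of which 70 passed; not all of them are printed in the text, and genes named outside it are said to be.

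The main test was tried on simulated counts for the same 16027 genes and 4 libraries with 200 genes changed and no length trend. It called 171 genes, 8.77% of them unchanged ones, and recovered 63% of genes changed by a log2 of 1 and 93% of those changed by a log2 of 2. A simulated length trend left in the counts gave 461 calls with 64.4% false, and its removal gave 174 calls with 9.2% false. Its slopes were set near those of the 4 libraries, so the main test resembles this arm more than the arm without a trend. The false share also depends on how many genes truly changed, which is unknown for the data. The simulated trend was linear in the same length that was then removed, and true changes ignored length. The trial therefore cannot tell how removal does on the real trend. With 1 simulated list shifted by a log2 of 0.6, camera called that list with the preset correlation and not with an estimated one (camera p = 0.0132). Simulated genes were drawn independently, so this trial cannot tell how the preset does for lists whose members move together. In the data, the estimated correlation of the lists called ran from 0.0636 (glucocorticoid receptor targets) to 0.95 (ribosomal proteins), and was 0.804 for red cell markers.

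Alternatives chosen before the data were examined were DESeq2 size factors, upper-quartile scaling, library totals, no filter, a mean CPM of at least 1, DESeq2 1.42.0, limma-voom, the replicate number as a block, a fold limit of 1.2 (glmTreat), no mitochondrially encoded genes, camera with an estimated correlation, fry, and each library left out in turn. Chosen after seeing the data were removal of a length trend, of a length and GC content trend, the replicate block with the numbers of PBS crossed, and the length trend removed together with the replicate block. The length trend was a loess (span 0.5) of each library's deviation from the gene's mean log2 CPM on log2 gene length, of degree 1, fitted on protein-coding genes with a mean log2 CPM above 1 and entered as an offset; GC content was that of the longest GENCODE M21 transcript, known for 99.9% of the genes used. Under an alternative, a change of sign between values that both missed the threshold was not counted as a reversal. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. With totals of 21904510 to 26948588 counts, depth was close to even, and the 2 libraries per group limit precision more than counting does.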

Results

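Whole right adrenal glands of adult male C57BL/6 mice were profiled by RNA sequencing 1 h after an intraperitoneal injection. Dexamethasone, a synthetic glucocorticoid, was given to 5 mice at 10 µg each, and the vehicle, phosphate-buffered saline (PBS), to another 5. The glands of each group were pooled into 2 libraries, a pool of 2 mice and a pool of 3 mice, so n = 2 libraries per group throughout. Which replicate number holds which pool is not stated. Total counts assigned to genes were 25968405 and 26733834 in dexamethasone replicates 1 and 2, and 26948588 and 21904510 in PBS replicates 1 and 2. Pearson correlation of log2 CPM (counts scaled to a common library size) across genes was 0.988 between the dexamethasone libraries and 0.983 between the PBS libraries, against 0.967 to 0.981 between libraries of different groups. Genes are not independent replicates in these correlations. Transcripts of Ddx3y, a gene of the Y chromosome, were counted 1994 to 2676 times in the 4 libraries and those of Xist, which is expressed from the inactive X chromosome of females, 0 to 3 times.

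The single comparison asked which adrenal transcripts differed 1 h after dexamethasone. Of 30 measured genes known as targets of the glucocorticoid receptor 17 were higher, among them Hif3a, Zbtb16, Ddit4, Tsc22d3 and Fkbp5, at 2.36-fold to 3.68-fold the PBS level. Transcripts of Nr4a1, an orphan nuclear receptor gene that is rapidly induced by corticotropin, were 10.4-fold lower (log2 fold change −3.38, and −2.71 without PBS replicate 1). Nr5a1, which encodes a transcription factor that drives steroid synthesis genes, was 2.56-fold lower. Fdx1, the gene of the electron donor of mitochondrial steroid hydroxylases, was 2.82-fold lower. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at a threshold of 0.05, 742 of 16027 genes tested differed, 523 higher and 219 lower after dexamethasone. The change reached a log2 size of 1 in 264 of the higher and 97 of the lower genes. All 742 genes had libraries that did not overlap between groups, which 33.3% of genes do by chance with 2 libraries against 2. This largely follows from passing the test, so it is not separate support. At an unadjusted p under 0.05 there were 4403 genes.

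Fold changes ran with the listed length of the gene, which is not its genomic span, and this matters for every count given here. Across 12403 protein-coding genes the log2 fold change correlated with log2 gene length at r = 0.486, and its median went from −0.42 in the decile of shortest genes to 0.34 in the decile of longest genes. With this trend removed from each library, 319 genes were higher and 160 lower. Of these, 288 and 114 were among the genes called higher and lower with the trend left in. The 742 calls and the list counts below come from the fit with the trend left in. In simulated counts with 200 genes changed and similar length slopes, that fit gave 64.4% false calls. Leaving out a library moved the counts by over 1.5 times in several cases. The number higher was 337 without dexamethasone replicate 2 and 1595 without PBS replicate 1, and the number lower was 783 without dexamethasone replicate 1, 1747 without PBS replicate 1 and 361 without PBS replicate 2. Scaling by library totals alone gave 893 higher and 180 lower genes, 83.2% higher against 70.5% with the TMM factors, and shifted the median log2 fold change of all genes from 0.01 to 0.10.

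**Figure D1:**
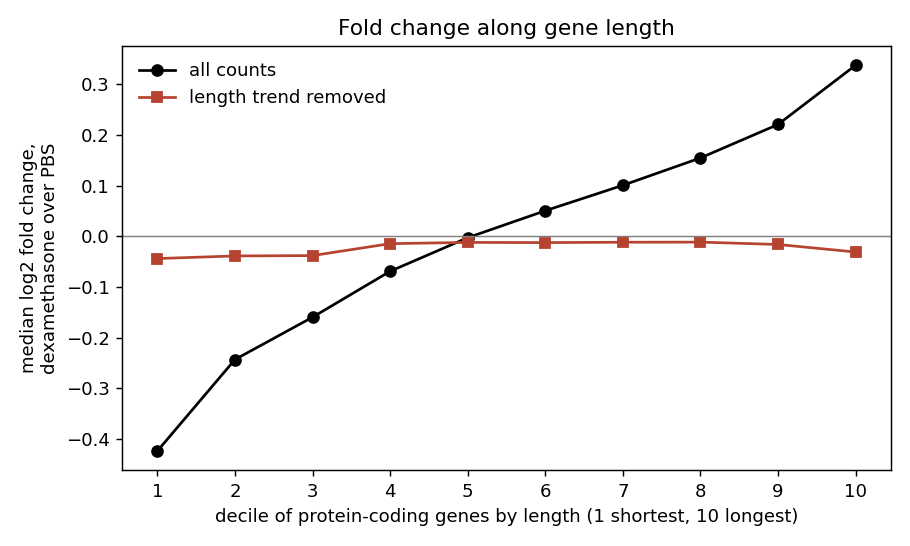
Median log2 fold change (dexamethasone over PBS, vertical axis) in each decile of 12403 protein-coding genes ordered by listed length (horizontal axis), with all counts as deposited (black circles) and with the length trend of each library removed (red squares). The black line goes from −0.42 in the shortest decile to 0.34 in the longest, and the red line stays between −0.04 and −0.01.

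The 12 higher genes with the smallest p were Itgb3, Unc80, Prune2, Zbtb16, Greb1, Hhip, Pclo, Lancl3, Fam107a, Tbx20, Abca1 and Chrna7. The steepest of them was Lancl3, with a log2 fold change of 2.44 ± 0.24 (SE, n = 2 per group). Itgb3, the integrin beta 3 subunit gene (ENSMUSG00000020689, GRCm38 chromosome 11, 104608000 to 104670476), stood at 54.0 ± 2.19 CPM (SD, n = 2) after dexamethasone and 16.0 ± 0.0847 CPM after PBS. Abca1, the cholesterol efflux transporter gene, was 3.93-fold higher (log2 fold change 1.98 ± 0.20). Chrna7, which encodes the alpha 7 subunit of the nicotinic acetylcholine receptor, had a log2 fold change of 1.82 ± 0.19, and Hhip, a gene whose product binds hedgehog ligands, 1.72 ± 0.16. Each of the 12 had an adjusted p of 0.00426, and each still passed with the length trend removed, with log2 fold changes from 1.00 for Pclo to 2.46 for Lancl3.

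The 12 lower genes with the smallest p included Coq10b, Nr4a1, Mob4, Arhgap28, Nr5a1, Tnfrsf11b, Fdx1, Thbs1, Fam222a, Scx and Adamts1. Coq10b, a coenzyme Q binding protein gene (ENSMUSG00000025981, chromosome 1, 55052770 to 55072702), fell from 133 ± 9.61 CPM (SD, n = 2) after PBS to 41.3 ± 0.845 CPM after dexamethasone. Nr4a1 (ENSMUSG00000023034, chromosome 15, 101254269 to 101274795) had a log2 fold change of −3.38 ± 0.33 (SE), with 481 and 217 CPM in PBS replicates 1 and 2 and 32.5 and 34.5 CPM in the dexamethasone libraries. Tnfrsf11b, the osteoprotegerin gene, had −1.63 ± 0.18, and Thbs1, the thrombospondin 1 gene, −1.35 ± 0.16. Adjusted p ran from 0.00426 to 0.00772 over the 12. With the length trend removed all 12 passed, from −1.07 for Fam222a to −3.33 for Nr4a1.

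**Figure D2:**
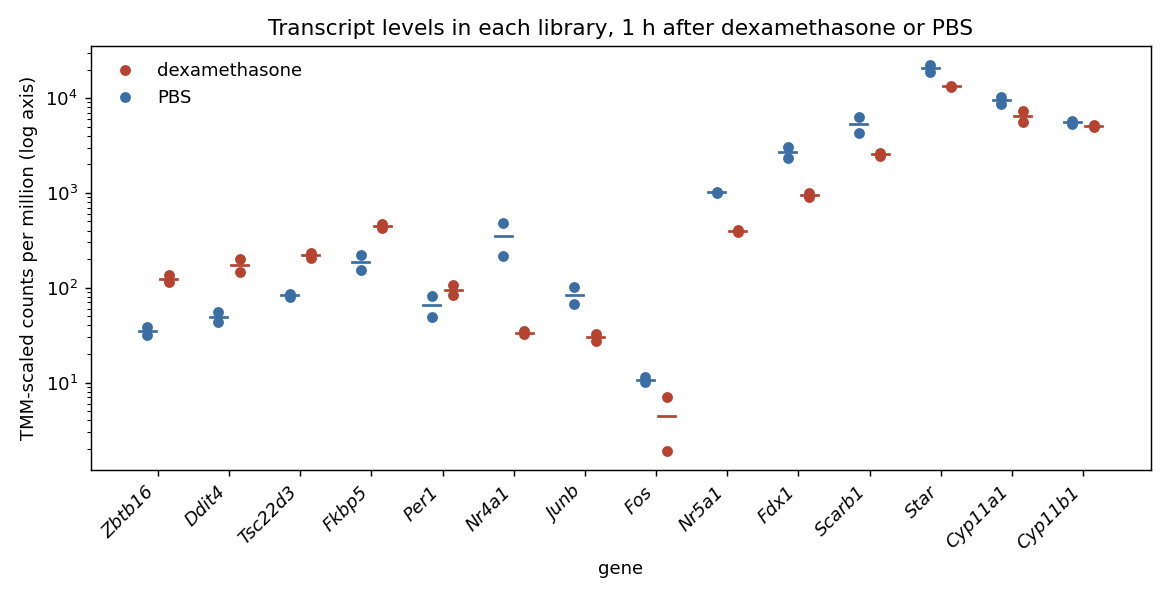
TMM-scaled CPM on a log axis (vertical) for 14 genes (horizontal) in the 4 libraries; points are libraries (red dexamethasone, blue PBS, n = 2 each) and short bars are group means. Both dexamethasone points lie above both PBS points for Zbtb16, Ddit4, Tsc22d3, Fkbp5 and Per1, and below them for the other 9 genes; Per1, Fos, Star, Cyp11a1 and Cyp11b1 did not pass the test.

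Among 30 measured target genes of the glucocorticoid receptor, 17 rose, 0 fell and 13 did not pass; 22 were higher when adjusted over the list alone. Zbtb16, a zinc finger repressor gene (ENSMUSG00000066687, chromosome 9, 48654297 to 48836222), had a log2 fold change of 1.84 ± 0.16 (SE, n = 2 per group, edgeR adjusted p = 0.00426). Tsc22d3, which encodes the leucine zipper protein GILZ, had 1.41 ± 0.15, and Ddit4, an inhibitor gene of mTOR signalling, 1.81 ± 0.19. Fkbp5, which encodes a co-chaperone of the receptor (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527), had 1.24 ± 0.19 (adjusted p = 0.0117). Klf9, Pdk4, Errfi1, Hif3a and Irs2 were among the other members that rose. The clock gene Per1, at 0.55 ± 0.23 (adjusted p = 0.165), did not pass. Per1 stood at 0.36 without dexamethasone replicate 2 and 0.22 without PBS replicate 2, and passed without PBS replicate 1 (0.94). Neither did Sgk1, Cebpb and the metallothionein genes Mt1 and Mt2, at 0.12, 0.23, −0.24 and −0.07, which were picked after their values were seen. The list as a whole was higher by camera (median log2 fold change 1.00, adjusted p = 1.27e-10 over 27 lists). That call was lost at adjusted p = 0.642 with an estimated correlation, in a range from 3.87e-14 to 0.642 over 17 alternatives. With the length trend removed its median was 1.03 and 18 members passed.

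Of 24 measured genes of steroid synthesis and its regulators, 5 fell, 0 rose and 19 did not pass; 12 were lower when adjusted over the list alone. The 5 were Nr5a1 (ENSMUSG00000026751, chromosome 2, 38692656 to 38714542; −1.35 ± 0.14, SE), Fdx1 (−1.50 ± 0.18), the lipoprotein receptor gene Scarb1 (−1.06 ± 0.20), the aldo-keto reductase gene Akr1b7 (−1.20 ± 0.23) and Mrap, the accessory protein gene of the corticotropin receptor (−1.50 ± 0.35). Star, which encodes the protein that delivers cholesterol to the inner mitochondrial membrane, stood at 13387 ± 241 CPM (SD, n = 2) after dexamethasone and 20599 ± 2303 CPM after PBS, and its log2 fold change of −0.62 ± 0.15 did not pass (edgeR adjusted p = 0.0553). The steroid hydroxylase genes Cyp11a1, Cyp11b1 and Cyp11b2 had −0.56 ± 0.18 (adjusted p = 0.0889), −0.14 ± 0.15 (0.577) and −0.95 ± 0.28 (0.0749). The corticotropin receptor gene Mc2r had −0.40 ± 0.16 (0.142), −0.25 without dexamethasone replicate 2 and −0.07 with the length trend removed. Star passed without PBS replicate 2 (−0.74) and by DESeq2 (−0.63). Cyp11a1 passed without dexamethasone replicate 1 (−0.76), without PBS replicate 1 (−0.68) and by DESeq2 (−0.57). Cyp11b2 passed without dexamethasone replicate 1 (−1.04) or PBS replicate 1 (−1.38), and stood at −0.38 without PBS replicate 2 and −0.60 with the length trend removed. Cyp11b1 was at −0.04 with that trend removed. Camera called the list lower (median −0.47, adjusted p = 8.16e-06). The call was lost at adjusted p = 0.642 with an estimated correlation, in a range from 1.59e-06 to 0.642 over 17 alternatives. With the length trend removed the median was −0.30 and Akr1b7 (−0.78) and Mrap (−1.15) no longer passed. Without PBS replicate 2 Mrap stood at −0.76, and the members lower numbered 9 without dexamethasone replicate 1 and 12 without PBS replicate 1.

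Some genes of cholesterol synthesis and uptake were lower too. Of 24 measured, 4 fell, 1 rose and 19 did not pass, and 10 were lower and 1 higher when adjusted over the list alone. Insig1, a sterol sensor partner gene, had a log2 fold change of −0.89 ± 0.15 (SE, n = 2 per group), and Hmgcs1, the cytosolic HMG-CoA synthase gene, −0.84 ± 0.15. Dhcr7, a gene of the last steps of the pathway, fell too (−0.70 ± 0.14). Camera called the list lower (median −0.49, adjusted p = 0.00029), and its median ran from −0.69 to −0.19 over 17 alternatives. The call was lost at adjusted p = 0.642 with an estimated correlation, in a range from 1.76e-06 to 0.642 over 17 alternatives. Dhcr7 did not pass without dexamethasone replicate 2 (−0.67). In all, 14 members were lower without PBS replicate 1. With the length trend removed the list's median was −0.45 and 5 members were lower.

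Some immediate early genes, which respond to stimuli within minutes, were lower. Of 29 measured, 5 fell, 1 rose and 23 did not pass, and 13 were lower and 2 higher when adjusted over the list alone. Beside Nr4a1, those that fell were Junb (−1.49 ± 0.21, SE), Egr3 (−3.80 ± 0.69), Ier2 (−0.85 ± 0.17) and Nr4a3 (−0.85 ± 0.17). Fosl2, a member of the Fos family, rose (0.92 ± 0.14), and Fos itself, at −1.26 ± 0.46 (edgeR adjusted p = 0.122), did not pass. Fos stood at −0.61 without dexamethasone replicate 1, and passed without dexamethasone replicate 2 (−2.50), PBS replicate 1 (−1.19) or PBS replicate 2 (−1.35). Egr3 was at 11.1 CPM in PBS replicate 2, 2.49 CPM in PBS replicate 1 and 0.372 and 0.582 CPM after dexamethasone, and its log2 fold change was −2.38 without PBS replicate 2 and −4.54 without PBS replicate 1. Atf3 was at 23.1 CPM in PBS replicate 2 and 3.61 CPM in PBS replicate 1. Camera called the list lower (median −0.67, adjusted p = 0.0196). The call was lost at adjusted p = 0.642 with an estimated correlation, in a range from 1.64e-05 to 0.642 over 17 alternatives. The call ended without dexamethasone replicate 1 (median −0.57), without PBS replicate 2 (−0.20) and with the length trend removed (−0.48). Ier2 (−0.74) and Nr4a3 (−0.72) did not pass without dexamethasone replicate 1, nor Ier2 with the length trend removed (−0.48). The members lower numbered 10 without dexamethasone replicate 2 and 17 without PBS replicate 1.

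The genes responsive to cAMP and corticotropin share members with these lists. Of 20 measured, 6 fell (Nr4a1, Nr4a3, Mrap, Inha, Scarb1 and Akr1b7), 2 rose (Fosl2 and the phosphodiesterase gene Pde10a, 1.30 ± 0.22 SE) and 12 did not pass. In this list 9 were lower and 2 higher when adjusted over the list alone. Inha, the inhibin alpha gene, had −0.95 ± 0.22 and did not pass without PBS replicate 2 (−0.58) or with the length trend removed (−0.57), and Pde10a did not pass with that trend removed (0.91). The list did not pass in camera (median −0.41, adjusted p = 0.0626), and it passed in 9 of 17 alternatives (adjusted p from 0.00651 to 0.642 over the 17). Among these were library totals (−0.32, adjusted p = 0.02), no filter (−0.41, adjusted p = 0.0316), leaving out dexamethasone replicate 2 (−0.48) or PBS replicate 1 (−0.40), and the length trend removed (−0.39, adjusted p = 0.0483).

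Transcripts of red blood cells were lower after dexamethasone. Of 5 measured markers 3 fell and 2 did not pass, and all 5 were lower when adjusted over the list alone. The haemoglobin genes Hba-a1, Hba-a2 and Hbb-bs had log2 fold changes of −1.17 ± 0.23, −1.45 ± 0.32 and −1.08 ± 0.23 (SE, n = 2 per group). The alpha genes are near-identical copies, as are the beta genes, so the division of counts between copies is uncertain. Hba-a1 stood at 143 CPM in PBS replicate 2, 82.3 CPM in PBS replicate 1, and 48.5 and 51.6 CPM after dexamethasone. Camera called the list lower (median −1.17, adjusted p = 0.00609). The call was lost at adjusted p = 0.642 with an estimated correlation, in a range from 0.000127 to 0.642 over 17 alternatives. The median was −0.56 with the length trend removed, and neither the list nor any of the 3 genes passed. Without PBS replicate 2, Hba-a1, Hba-a2 and Hbb-bs stood at −0.73, −0.90 and −0.67, and Hba-a2 did not pass.

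**Figure D3:**
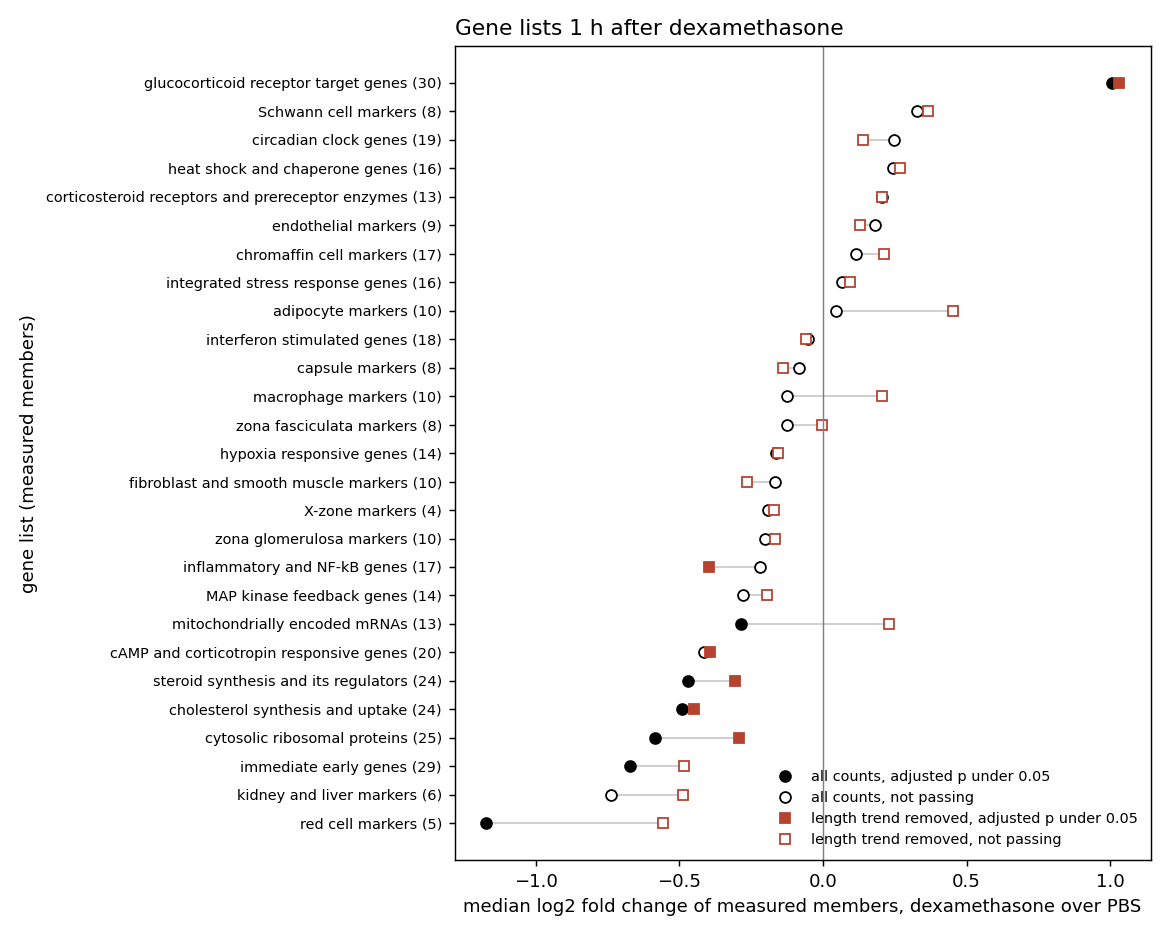
Median log2 fold change (dexamethasone over PBS, horizontal axis) of the measured members of 27 gene lists (vertical axis, number of members in brackets), with all counts (circles) and with the length trend of each library removed (squares); filled symbols passed camera with the preset correlation at an adjusted p of 0.05. The glucocorticoid receptor targets lie at 1.00 and 1.03, and the red cell markers move from −1.17 to −0.56.

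Markers of the gland's own cell types gave single changes and no list that passed. None of 17 chromaffin cell markers passed in edgeR (0 of 17 also adjusted over the list alone; 2 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom; camera adjusted p = 0.554). Th, the rate-limiting enzyme gene of catecholamine synthesis, stood at 0.05 ± 0.27 (SE, n = 2 per group) and Pnmt, whose enzyme makes adrenaline from noradrenaline, at 0.62 ± 0.30. Pnmt and the granin gene Scg2 passed with the length trend removed, at 1.04 and 0.85. Without dexamethasone replicates 1 and 2 and PBS replicates 1 and 2 in turn, Pnmt was at 0.10, 0.99, 0.28 and 1.01, passing at 0.99 and 1.01, and Th at −0.32, 0.35, −0.27 and 0.43. Scg2 passed without dexamethasone replicate 2 (0.82) or PBS replicate 2 (0.87), and the chromaffin list passed camera without PBS replicate 2 (median 0.43). Of the zona glomerulosa markers 1 of 10 fell, the angiotensin receptor gene Agtr1b (−1.13 ± 0.23), and camera gave the list an adjusted p of 0.602. Of the zona fasciculata markers 2 of 8 fell, Akr1b7 and Mrap (camera adjusted p = 0.632). Of the X-zone markers, which label the inner juvenile cortex, 1 of 4 measured fell, Cyp17a1 (−1.64 ± 0.33), and camera gave the list an adjusted p of 0.355. Cyp17a1 was low in all libraries, at 1.04 and 1.34 CPM after dexamethasone and 3.20 and 4.28 CPM after PBS. Akr1c18 and Pik3c2g of this list had too few counts to be tested, so a change of that zone was not shown. Of the capsule markers 1 of 8 fell, the Wnt signal enhancer gene Rspo3 (−0.81 ± 0.16; camera adjusted p = 0.296). With the length trend removed Agtr1b (−0.89), Cyp17a1 (−1.40) and Rspo3 (−0.71) did not pass, while the fasciculata marker Srd5a2 passed as higher (0.88, from 0.55 ± 0.15 with the trend left in), and Rspo3 did not pass without dexamethasone replicate 1 (−0.70). Counts adjusted over the list alone were 2 higher and 2 lower for the glomerulosa, 2 and 3 for the fasciculata, 0 and 1 for the X-zone and 0 and 1 for the capsule list.

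Among other cell types, 2 of 10 macrophage markers rose, Mrc1, the mannose receptor gene (1.24 ± 0.14, SE, n = 2 per group), and Cd163, the haemoglobin scavenger receptor gene (0.91 ± 0.22). Cd163 did not pass without dexamethasone replicate 1 (0.91), dexamethasone replicate 2 (0.92) or PBS replicate 2 (0.89), or with the length trend removed (0.83). The macrophage list had a median of −0.12 and a mean of 0.07, and camera, whose direction was higher, did not call it (adjusted p = 0.688). No member passed in edgeR among 9 endothelial (camera adjusted p = 0.675), 10 adipocyte (0.768) and 8 Schwann cell markers (0.632). The same held for 10 fibroblast and smooth muscle (0.275) and 6 kidney and liver markers (0.264), and for Cd4 and Ighm, the 2 lymphocyte markers measured. At an unadjusted p under 0.05 there were 2 endothelial, 2 adipocyte, 3 Schwann cell, 2 fibroblast and smooth muscle, 0 kidney and liver and 0 lymphocyte markers. DESeq2 called 1 endothelial marker and 0 of the others, and limma-voom 0. Col1a1, a collagen gene of the fibroblast list, passed as lower with the length trend removed (−0.54). No neutrophil marker had enough counts to be tested. Adjusted over the list alone, 2 macrophage markers were higher and 1 lower, 2 Schwann cell markers higher, and 0 of the other lists named here. The kidney and liver list passed camera without dexamethasone replicate 1 (median −3.75) and the adipocyte list without dexamethasone replicate 2 (median 0.30). The kidney and liver list had a median of −0.74 with all 4 libraries and 0.70 without PBS replicate 1. The liver transcript Alb was at 61.9 CPM in PBS replicate 1 and 18.2, 2.40 and 6.54 CPM in dexamethasone replicates 1 and 2 and PBS replicate 2, higher in replicate 1 of each group. The brown fat transcript Ucp1 was at 5.99 CPM in dexamethasone replicate 1 and 0.254, 0.113 and 1.25 CPM in dexamethasone replicate 2 and PBS replicates 1 and 2.

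Inflammatory and NF-kB genes had 1 member of 17 that rose, Vcam1, a vascular adhesion molecule gene (1.32 ± 0.16, SE, n = 2 per group), and 0 that fell, with 2 higher and 6 lower adjusted over the list alone. Camera did not call that list (median −0.22, adjusted p = 0.155) and called it lower with the length trend removed (median −0.40, adjusted p = 0.0446; 0.00861 to 0.642 over 17 alternatives), without dexamethasone replicate 1 (−0.52) and without PBS replicate 1 (−0.56). Of 18 interferon stimulated genes 1 fell, Rsad2 (−0.96 ± 0.14; camera adjusted p = 0.466). Of 14 MAP kinase feedback genes the phosphatase genes Dusp5 (−1.89 ± 0.26) and Dusp6 (−0.64 ± 0.14) fell, and Dusp1 (0.72 ± 0.17) and Errfi1 (1.27 ± 0.16) rose (camera adjusted p = 0.221). Of 16 integrated stress response genes Atf4 (−1.37 ± 0.24) and the serine synthesis gene Psat1 (−0.83 ± 0.16) fell and Ddit4 rose. This list had a median of 0.07, a mean of −0.09 and a camera adjusted p of 0.989. Of 14 hypoxia responsive genes Egln3 fell (−1.59 ± 0.36; camera adjusted p = 0.274). The list of corticosteroid receptors and prereceptor enzymes, with 13 measured genes, also holds cofactor, chaperone and transporter genes. Of the 13, Crebrf rose (0.91 ± 0.14), which is neither a receptor nor a prereceptor enzyme gene. Camera did not call the list (adjusted p = 0.0956), and it passed without dexamethasone replicate 2 (median 0.22). The receptor gene Nr3c2 and the enzyme genes Hsd11b1 and Hsd11b2 stood at −0.11, −0.03 and 0.03 and did not pass. The receptor gene Nr3c1 itself stood at 0.16 ± 0.18 (edgeR adjusted p = 0.618), at 0.42 and −0.09 without PBS replicates 1 and 2, and at −0.02 with the length trend removed. None of 19 circadian clock genes passed in edgeR (camera adjusted p = 0.215), nor any of 16 heat shock and chaperone genes (camera adjusted p = 0.602), a list that passed without dexamethasone replicate 2 (median 0.58). At an unadjusted p under 0.05 there were 5 clock and 4 chaperone genes, DESeq2 called 2 and 1, and limma-voom 0 of either list. Dusp1 did not pass without dexamethasone replicate 2 (0.73) or PBS replicate 2 (0.51). Dusp6 and Egln3 did not pass without either dexamethasone library or without PBS replicate 2 (−0.69 to −0.54 and −1.64 to −1.53), or with the length trend removed (−0.54 and −1.44). Adjusted over the list alone, higher and lower members numbered 0 and 1 of the interferon, 3 and 4 of the MAP kinase and 4 and 3 of the stress response list. They numbered 1 and 1 of the hypoxia, 5 and 0 of the corticosteroid receptor, 0 and 0 of the clock and 0 and 0 of the chaperone list. The 5 were Crebrf, Abcb1b, Ncoa1, Ncoa2 and Ncor1, with no receptor or prereceptor enzyme gene among them.

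The lists kept as signs of RNA quality also moved. All 25 cytosolic ribosomal protein genes, whose transcripts are short, had log2 fold changes below 0, with a median of −0.59. Over all genes 0 passed in edgeR, and 25 were lower when adjusted over the list alone. DESeq2 called 21 and limma-voom 0, and 25 had an unadjusted p under 0.05 in edgeR. Rpl27 had −0.68 ± 0.19 (SE, n = 2 per group) and Rplp1 −0.78 ± 0.23, and with the length trend removed they stood at −0.34 and −0.07. Without dexamethasone replicate 1 or PBS replicate 1 both passed (−0.90 and −0.87 for Rpl27, and −1.14 for Rplp1 without the dexamethasone library), and without dexamethasone replicate 2 Rplp1 stood at −0.50. Camera called the list lower (adjusted p = 3.5e-08). The call was lost at adjusted p = 0.642 with an estimated correlation, in a range from 5.73e-10 to 0.642 over 17 alternatives, and the list still passed with the length trend removed (median −0.29, adjusted p = 3.05e-05). The 13 mitochondrially encoded mRNAs had a median of −0.29 with 0 members passing in edgeR in either adjustment, 3 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom. Camera called them lower (adjusted p = 0.0133), and the call was lost at adjusted p = 0.642 with an estimated correlation, in a range from 0.00112 to 0.642 over 16 alternatives. This call ended without dexamethasone replicate 1 (median −0.16), and the direction turned with the length trend removed (median 0.23), where the list did not pass. Some mitochondrial genes have near-identical nuclear copies, so their counts are uncertain. Mitochondrially encoded genes took 4.59% and 5.59% of counts in dexamethasone replicates 1 and 2 and 5.45% and 6.03% in PBS replicates 1 and 2.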

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

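The fits that removed a length or GC trend and the crossed block were chosen after the result was seen. Among the 145 named genes, none that passed turned direction with a call under any alternative run; of all 742 genes called, 1 predicted gene turned sign with the length trend removed, without passing. Of the 7 lists called, the mitochondrially encoded mRNAs turned in median and did not pass, at 0.23 with the length trend removed, 0.14 with GC as well and 0.19 with the length trend removed and the replicate block. DESeq2 size factors, upper-quartile scaling, a mean CPM of at least 1, limma-voom and no mitochondrial genes shared 690 to 741 of the 742 calls. The length trend removed ended 14 calls among the named genes and added 5. Simulated changes of a log2 of 1 were recovered in 63% of cases, so genes that did not pass may have changed by that size, and the length trend removed leaves 319 genes higher.

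The main test gave 523 genes higher and 219 lower, with 5 immediate early, 5 steroid and 4 cholesterol genes lower and 1 list higher and 6 lower. Library totals gave 893 higher (83.2% of calls, against 70.5%). No filter gave 1384 higher and 1329 lower of 27040 genes, with 15 immediate early, 12 steroid and 12 cholesterol genes lower. DESeq2's Wald test gave 869 and 841, with 8, 10 and 7. A fold limit of 1.2 gave 258 and 82, with 3 immediate early and 2 cholesterol genes lower. Length and GC trends removed gave 335 higher. Camera with an estimated correlation and fry each called 0 lists higher and 0 lower, with 1 and 5 lists at an unadjusted p under 0.05. With a library left out, the lone library took its spread from the other group, and 400 to 738 of the 742 calls were shared. Genes higher ran from 337 without dexamethasone replicate 2 to 1595 without PBS replicate 1, and genes lower from 147 to 1747 without the same libraries. Members lower ran from 7 to 17 for immediate early, 6 to 12 for steroid and 3 to 14 for cholesterol genes, glucocorticoid targets higher from 17 to 22, and lists from 1 to 4 higher and 5 to 9 lower. The cause was not tested for any of these, apart from the fold limit, which is stricter by construction. The labels do not say that a replicate number marks a shared animal or day, and same-numbered libraries deviated with a correlation of −0.03 over all genes and −0.22 over genes with a mean log2 CPM above 1. The replicate block, with 1 residual degree of freedom, gave 244 higher and 89 lower genes, 324 of them among the 742, with 3 immediate early and 2 cholesterol genes lower, and 278 higher with the length trend removed too. It called the kidney and liver list lower (−0.85), and with the length trend removed that list (−0.63), the red cell list (−0.56) and the immediate early list (−0.49). Crossing the numbers gave 1546 higher and 1465 lower genes, with 13 immediate early, 14 steroid and 11 cholesterol genes lower.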

Other observations

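All genes and tests below were chosen after the result was seen, except the test of GC content and the members of 3 hypothesis lists. The receptor genes named here all passed also with the length trend removed. They changed in both directions (values are log2 fold change ± SE, n = 2 per group). Higher were Il1r1, the interleukin 1 receptor (1.41 ± 0.20), Egfr (1.31 ± 0.19), the prostaglandin receptor Ptger3 (1.21 ± 0.18), the PACAP receptor Adcyap1r1 (1.10 ± 0.15), the endothelin receptor Ednrb (0.97 ± 0.15) and the sphingosine phosphate receptor S1pr1 (0.93 ± 0.14). Lower were the chemokine receptors Ccr2 (−2.25 ± 0.38) and Cx3cr1 (−0.74 ± 0.17), the apelin receptor Aplnr (−1.68 ± 0.22), the natriuretic peptide clearance receptor Npr3 (−1.32 ± 0.17), the oxytocin receptor Oxtr (−1.12 ± 0.21) and S1pr3 (−0.70 ± 0.15).

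Single transcription factor genes outside the lists changed and passed also with the length trend removed, and a test for an excess of such genes did not pass. Of 1026 genes with a transcription factor family in the deposited table, 44 were higher (Fisher's exact test, p = 0.0684) and 21 lower (Fisher's exact test, p = 0.0685), in a test that takes genes as independent. Klf15 (1.31 ± 0.15), Maf (1.46 ± 0.19), Prox1 (0.95 ± 0.15) and Gata1 (2.17 ± 0.32) were higher, and Batf3 (−2.03 ± 0.35), Hic1 (−1.39 ± 0.19), Hes6 (−1.31 ± 0.18) and Creb3l1 (−1.18 ± 0.19) lower. Alas1, the first enzyme of haem synthesis, went from 1444 and 1219 CPM after PBS to 479 and 643 CPM after dexamethasone (−1.25 ± 0.18). Coq10b and Mob4, among the 12 lower genes with the smallest p, lie close together on chromosome 1, at 55052770 to 55072702 and 55131231 to 55154899. The protein-coding genes between them are Hspd1 (−0.46 ± 0.19) and Hspe1 (−0.96 ± 0.28), which did not pass in the main test. Over 18 alternatives they ran from −0.75 to −0.23 and from −1.54 to −0.55, and each passed under some. Hspe1 differed between dexamethasone replicates 1 and 2, at 241 and 122 CPM.

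The first of 3 patterns weighed is the length trend. GC content as its source is argued against, since r between fold change and log2 length was 0.431 after a GC trend was removed, against 0.486 before. Differences between libraries apart from the treatment may account for part of it: replicates of the same group differed along length too, with r of 0.449 in size between the dexamethasone libraries and 0.304 between the PBS libraries. An effect of dexamethasone on long transcripts cannot be told apart from such differences, because the slope per doubling of length differed by 0.107 between the closest libraries of the 2 groups and by 0.134 and 0.11 between replicates.

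The second pattern is the lower level of steroid and cholesterol genes. With the length trend as fitted removed, the list medians were −0.30 and −0.45. Both lists passed camera with the preset correlation (larger adjusted p = 0.000234; 1.59e-06 to 0.642 over the alternatives for steroid genes and 1.76e-06 to 0.642 for cholesterol genes). The 0.642 came from an estimated correlation with the trend left in, which was not tried on these lists with the trend removed. The list test therefore cannot decide whether the trend is the whole source. Of the steroid genes called, Nr5a1, Fdx1 and Scarb1 still passed in edgeR with the trend removed, and Akr1b7 and Mrap did not. Fewer cortical cells cannot be told apart from other sources. With the trend removed, the median of 43 other members was lower than that of 5 abundant cortical transcripts (difference −0.32). The spread set beside it, 0.219, was built from the median standard errors of single genes in the 2 sets. It is not the standard error of a difference between medians, so this comparison cannot decide. Of those 5, picked after the result, Star (−0.62 ± 0.16) and Cyp11a1 (−0.61 ± 0.18) moved apart from Cyp11b1 (−0.04 ± 0.14), Cyp21a1 (−0.09 ± 0.16; it has a near-identical pseudogene) and Hsd3b1 (−0.06 ± 0.15). A broader fall stays open, since ribosomal protein genes, kept as a sign of RNA quality, also passed as lower with the trend removed. Their median was −0.59 before and −0.29 after (camera adjusted p = 3.05e-05 after). With the trend left in, their call was lost at a camera adjusted p of 0.642 with an estimated correlation, which was 0.95. A response to dexamethasone stays open too, as a hypothesis.

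The third pattern is the lower level of red cell transcripts. The list's median went from −1.17 to −0.56 with the length trend removed, Hba-a1 from −1.17 ± 0.23 to −0.56 ± 0.22. The list's call ended as the median halved at similar standard errors of Hba-a1, and why it ended was not tested further, so the length trend as the whole source cannot be told apart from a smaller true difference in these 5 transcripts. Less blood in the glands collected after dexamethasone cannot be told apart from other sources either, because only 2 markers of other blood cells were measured. These were Cd4 and Ighm, at 0.67 ± 0.36 and 0.34 ± 0.13 with the trend removed. Other genes, looked at after the result, went both ways with the trend removed. Ccr2 and Cx3cr1, receptor genes of monocytes and of some tissue macrophages, were lower (−2.40 and −0.77). The Toll-like receptor gene Tlr7 (1.44), the transcription factor gene Gata1 (2.35) and the macrophage marker Mrc1 (1.10) were higher. Ccr2 and Gata1 were low in all libraries, at 0.509 to 3.46 and 0.817 to 4.83 CPM. PBS replicate 2 carried the highest Hba-a1 level, 143 CPM, against 82.3 CPM in PBS replicate 1, and without it Hba-a1 stood at −0.73.

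Further hypotheses came from single genes that passed and were tested on 3 lists of other genes, written before their values were looked at, with the length trend removed. The lists were measured in the same 4 libraries as the single genes. A difference between libraries shared by related genes could move both, so the lists are not independent support. Bysl, Gnl3, Nop56, Ppan, Brix1 and Eif6, genes of ribosome assembly, were lower (−0.67 to −0.86), though Brix1 did not pass with the trend removed, and a list of 38 other ribosome biogenesis genes was lower too (median −0.29, camera p = 1.14e-06, adjusted p = 3.42e-06 over the 3 lists), in line with a joint fall; p was 0.0807 with an estimated correlation, and 0 members passed singly in edgeR, with 19 at an unadjusted p under 0.05, against 3 that passed before the trend was removed. The ribosomal protein genes kept as a sign of RNA quality had the same median (−0.29), so a fall of these genes apart from that sign was not shown. Unc80, Pclo, Rab3c and Cadps, genes of neuronal excitability and vesicle release, were higher, and 27 other genes of that kind had a median of 0.39 (camera p = 0.000572, adjusted p = 0.000858; p = 0.0719 with an estimated correlation), in line with a joint rise; 2 passed singly, against 11 before the trend was removed, when the median was 0.76. Among markers of chromaffin cells, which share such functions, Pnmt (1.04) and Scg2 (0.85) passed as higher with the trend removed and the list did not (median 0.21, camera adjusted p = 0.0945), so a larger share of these cells was not separated from a joint rise. Esm1, Aplnr, Dll4, Sox17 and Bcl6b, genes expressed in endothelial cells, were lower, but a list of 18 other tip cell genes did not move beyond its spread (median −0.16, camera adjusted p = 0.417 over the 3 lists), which gives no sign of a joint fall.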
